A study of Mus musculus with 11 samples.

How the data were processed

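The data are gene-level values of 11 RNA-seq libraries of mouse primary neonatal lung fibroblasts, 6 WT and 5 PAD2KO, spread over 2 batches that the labels name. Per the labels' protocols, RNA was extracted with a silica column kit, libraries were made with a SMARTer mRNA kit in a SmartSeq2 workflow, and cells had been sorted by flow cytometry. Reads so primed and amplified carry no molecular identifiers, so copies of the same molecule were counted as separate reads. Whether the counting used strand is not given in the sources used here.

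The authors deposited a single table that gives, for each library, estimated counts, abundances as TPM, scaled to transcript length and library total, and effective gene lengths. Per the submitters' processing notes, fastp, Salmon 1.3.2 and DESeq2 1.46.0 were used and the genome build was GRCm39; the notes as held here give neither their roles nor the annotation. The estimated counts in the deposited table are not whole numbers and are not scaled between libraries, per the file headers, and they sum to a different total in each library. The deposited TPM values sum to the same total in each library and were used only to learn how counts and lengths relate. Estimated counts divide reads between similar genes by a model, so values of related genes can borrow from each other. The lengths entered only as an alternative. No column was left unused for want of a sample.

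Of 56065 table entries, 23133 carry no gene symbol. They took 3.80% to 6.40% of a library's counts and stayed out of totals and tests. The other 32932 entries were summed to 32868 symbols (55 symbols had several entries), and the sums were rounded to whole numbers. Totals of named genes were 962633 to 1421243 counts. The nuclear 18S ribosomal RNA gene Rn18s took 8.52% to 12.1% of them. The limit that 0 counts allow was set at 3 counts of a library's total.

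Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr on genotype, robust quasi-likelihood fit, terms for batch and genotype) with Benjamini-Hochberg adjustment at 0.05, which left 9932 genes. The common biological coefficient of variation was 0.129. A model with an interaction term tested whether the genotype difference differed between batches, and the batch term of the first model gave the difference between batches. Batch 1 and batch 2 were also fitted alone. Of 52 gene lists covering pathways, technical signs and cell type markers, 45 had the minimum of 3 genes tested and were compared by camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2. Alternatives were camera with an estimated correlation and the fry rotation test. Levels and shares per library were compared by exact permutation over all 462 splits of the libraries into 6 and 5, and over the 200 splits within batches, two-sided, with SciPy 1.17.1, NumPy 2.4.6 and Python 3.11.15. Groups, comparisons, tests, gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined.

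The rule names Padi2 and its family, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean log2 CPM of at least 2 and the same sign in all 5 PAD2KO libraries against the WT mean of their batch, filled to 5 in a direction with the smallest p, and up to 4 members of each list by p. It was written for PAD2KO against WT. For the interaction and the batch term the same size rule was applied later without the condition on signs, and the genes printed are a part of it picked after their values were seen. The result of 1 gene for the interaction is not reported here.

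WT 5 and WT 6 were the most alike of the pairs within a genotype and batch, with a chi-square per degree of freedom of 1.47 where the other such pairs had 2.16 to 3.37. They differed by more than counting noise and were kept as 2 libraries. Copies of the same molecule were counted as separate reads, so this cannot tell separate samples from 2 libraries of the same RNA.

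Positions came from the GENCODE M21 annotation of GRCm38, a different assembly from the one the submitters' notes name. It was used only for chromosomes and gene order, and 9582 of the 9932 tested genes (96.5%) had a single position in it.

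The tests were checked on simulated counts drawn from the real means and totals, in which 200 genes were changed by known amounts. For PAD2KO against WT the fit recovered 37.3%, 83.6% and 92.4% of genes changed by 0.5, 1 and 2 on the log2 scale among 9783 genes, with 10 false calls of 152. For the interaction it recovered 0%, 22.4% and 80.3% among 9768 genes, with 6 false calls of 74, and for the batch term 37.3%, 85.1% and 93.9% among 9760 genes, with 3 of 147. Of 11 lists shifted by 0.5, camera called 10 for PAD2KO against WT, with 3 lists called that had not been shifted, and 10 for the interaction, with 1 such list. With an estimated correlation it called 10 and 8 of the 11. The simulated genes were drawn independently, while real lists were correlated, with estimates of 0.728 for interferon-stimulated and 0.757 for contractile genes. The check therefore does not show how either form of camera behaves on correlated lists.

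The settings set beforehand as alternatives were other size factors, other count filters, DESeq2 1.42.0, limma voom with quality weights, no batch term, the replicate number as a block, a surrogate variable from sva 3.50.0, each batch alone, other thresholds, removal of mitochondrial, sex-linked and hemoglobin genes, and leaving out each library in turn. Chosen after seeing the data were removal of Rn18s, gene length offsets, Xist as a covariate, WT 5 and WT 6 summed, thinning to the smallest total, permutation within batches, further alternatives for the interaction and the place of the calls in the genome. Random draws used fixed seeds. The simulated departures of PAD2KO 7 were as fitted, in the genes called without PAD2KO 6 alone, or as fitted times 0.7, which called about as many genes as the real libraries. Where leaving out a library left a lone library of its genotype in a batch, the spread came from the other groups. Figures were drawn with Matplotlib 3.10.9.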

Results

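Neonatal lung fibroblasts were isolated from wild-type (WT) mice and from mice lacking peptidylarginine deiminase 2 (PAD2KO), sorted by flow cytometry and profiled by bulk RNA sequencing. The enzyme, encoded by Padi2, converts arginine side chains of proteins to citrulline. The 11 libraries fell into 6 WT and 5 PAD2KO, made in 2 batches that each held both genotypes. Batch 1 held WT 1, WT 3 and WT 4 with PAD2KO 1, PAD2KO 2 and PAD2KO 3, and batch 2 held WT 5, WT 6 and WT 7 with PAD2KO 6 and PAD2KO 7. The series title names basal and TNF-induced expression as its subject. The labels of these libraries name no treatment, and whether any of them were given TNF is not stated in the sources used here. The sorting gate is not given in the sources used here.

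Counts assigned to named genes ranged from 962633 in WT 7 to 1421243 in PAD2KO 2, and each library held counts for 14356 to 14856 named genes. At these totals, 0 counts in a library allow a level of up to 2.11 to 3.12 CPM, the count scaled to equal library totals. Such floors, and the intervals given for counts, cover counting error only. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 48.4% of the variance and separated the batches, and the second held 11.7%. Within batch 1 the genotypes intermingled on these components, while in batch 2 PAD2KO 6 and PAD2KO 7 lay on the other side of the second component from WT 5, WT 6 and WT 7.

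**Figure D1:**
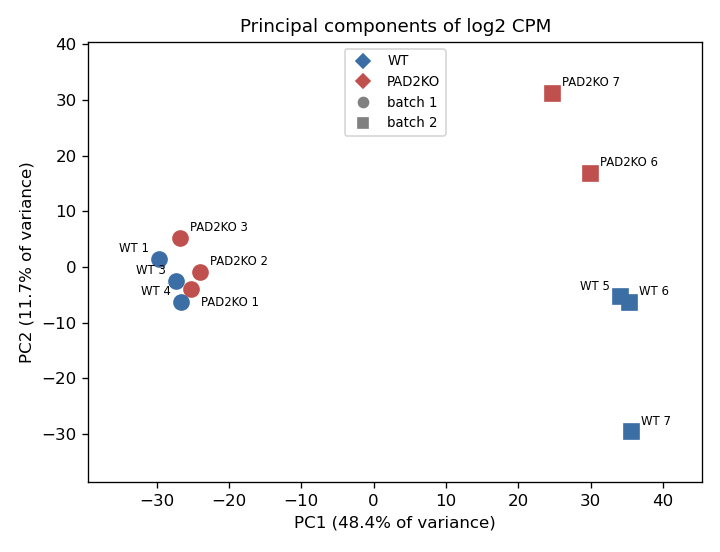
Each point is a library placed by its first and second principal components of log2 CPM, coloured by genotype, with circles for batch 1 and squares for batch 2. The first component (48.4% of the variance) parts the batches, and the second (11.7%) parts WT from PAD2KO in batch 2.

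Padi2 itself was close to absent from all of these fibroblasts, whichever their genotype. It had 3 counts over the 6 WT libraries (1 in WT 5 and 2 in WT 6) and 9 counts over the 5 PAD2KO libraries (1 in PAD2KO 1, 4 in PAD2KO 3 and 4 in PAD2KO 7). The ratio of PAD2KO to WT was 3.48 with a 95% interval of 0.868 to 19.98 (exact conditional Poisson test, two-sided p = 0.0781). Which part of the gene was removed is not given in the sources used here, and at these counts Padi2 cannot check the genotype labels. The other family members were as scarce: Padi1 had 1 count in PAD2KO 2, Padi6 had 1 count in each of WT 7, PAD2KO 1 and PAD2KO 7, and Padi3 and Padi4 had 0 in all 11 libraries. No member of the family reached the count filter, so neither a fold change nor a test of the family was made.

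PAD2KO fibroblasts carried less mRNA of a small set of genes than WT fibroblasts of the same batch. Pdpn, the mucin-type membrane glycoprotein podoplanin, fell from 376 ± 19.9 to 91.2 ± 12.03 CPM in batch 1 (SD, n = 3 and 3) and from 1204 ± 152 to 112 ± 1.97 CPM in batch 2 (SD, n = 3 and 2). Tnfrsf1b, which encodes TNF receptor 2, fell from 64.8 ± 3.63 to 30.1 ± 6.06 CPM in batch 1 and from 97.7 ± 21.4 to 23.8 ± 2.27 CPM in batch 2. Agtrap, an angiotensin receptor-associated protein, fell from 78.1 ± 4.19 to 28.6 ± 14.5 CPM and from 62.9 ± 5.58 to 24.6 ± 1.14 CPM in the same order. Lepr, the leptin receptor, was higher, at 20.1 ± 3.08 and 36.8 ± 9.89 CPM in WT and PAD2KO of batch 1 and at 15.5 ± 3.63 and 51.5 ± 14.8 CPM in batch 2. Across all 11 libraries, 19 of 9932 genes tested passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test with batch in the model, 2 of them higher and 17 lower in PAD2KO. An unadjusted p under 0.05 was reached by 759 genes, against 496.6 expected by chance. Other settings gave from 343 genes (without the batch term) to 1402 (batch 2 alone), with 506 by DESeq2 and 547 with 1 surrogate variable. Because genes vary together, the expected number does not tell how far such a count strays by chance.

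The strongest falls were those of Zfp984, a zinc finger protein, at -3.65 (SE 0.458, adjusted p = 8.58e-05), Pdpn at -2.66 (SE 0.259, adjusted p = 0.00382) and Fbxo44, an F-box protein, at -2.35 (SE 0.295, adjusted p = 8.58e-05) on the log2 scale. Zfp984 was down to a few counts in PAD2KO, at 1.45 CPM in batch 1 and 0.411 CPM in batch 2, beside 15.7 and 12.3 CPM in WT. Tnfrsf1b (-1.48, SE 0.170) and Agtrap (-1.42, SE 0.172) each had an adjusted p of 8.58e-05. Among genes of secreted or signalling proteins, Igfbp3, which binds insulin-like growth factors, fell by 1.27, Tnfsf15, a TNF family cytokine, by 1.06, Bmp3, a bone morphogenetic protein, by 1.01, and Adamts7, a secreted metalloprotease, by 0.95, with adjusted p-values of 0.0119, 0.0286, 0.0135 and 0.0426. Rab6b, a small GTPase, fell by 2.14 (adjusted p = 0.0119). Lepr rose by 1.23 (SE 0.202, adjusted p = 0.00382) and Anxa1, which encodes the phospholipid-binding protein annexin A1, by 0.40 (SE 0.0819, adjusted p = 0.0286). Each of these genes moved the same way in all 5 PAD2KO libraries against the WT mean of their batch. To fill the higher direction to 5 genes, the fixed rule also took Zfp933 (1.11, adjusted p = 0.144), Clcn6 (0.71, adjusted p = 0.153) and Steap2 (0.38, adjusted p = 0.161), none of which passed.

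The remaining calls were Il6, C2, Rtp4 and Peg10, described with their gene groups, and Podn (-0.91), Adamts15 (-0.79) and Dchs1 (-0.68), which lay beyond the 12 that the rule took and were chosen after their values were seen. Podn encodes a proteoglycan of the extracellular matrix, Adamts15 a secreted metalloprotease and Dchs1 a large cadherin. Leaving out each library in turn kept 7 calls in all 11 fits, those of Agtrap, Fbxo44, Lepr, Pdpn, Podn, Tnfrsf1b and Zfp984. Adamts15 and Igfbp3 passed in 10 of these fits (not without WT 4 and not without WT 3), Bmp3 and C2 in 8, Tnfsf15 and Peg10 in 6, Dchs1, Rab6b and Rtp4 in 5, Il6 in 4, and Adamts7 and Anxa1 in 3; Rab6b, Rtp4 and Il6 fell under the count filter in some of the others. Without WT 3, the number of calls went from 19 to 8, all of them among the 19. Offsets from the deposited gene lengths ended 17 of the calls and left those of Pdpn and Zfp984. All 19 genes kept their sign with these offsets, with fold changes that moved by at most 0.43 and SEs that were 1.31 times as large at the median. Without the batch term 4 calls were left, those of Agtrap, Fbxo44, Tnfrsf1b and Zfp984. With 1 surrogate variable 10 were left; of the 9 others, Il6 (-0.67), Rtp4 (-1.12) and Adamts7 (-0.61) moved by over 1.5 times, and Lepr went to 0.89.

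Fitted alone, batch 1 gave 22 genes of 9917 (7 higher, 15 lower) and batch 2 gave 248 of 10076 (104 higher, 144 lower). In both batches 6 genes were called, and all 6 were lower in PAD2KO: Adamts15, Agtrap, Fbxo44, Pdpn, Tnfrsf1b and Zfp984. Independent lists of these sizes would share 0.180 genes in that direction. For Pdpn the fall was larger in batch 2, at -3.42 against -2.05 in batch 1 in the joint fit, and this difference passed its own test (-1.38, SE 0.183, adjusted p = 0.000107). Of the 19 calls, Pdpn was the 1 whose size differed between the batches by that test. This does not show that the others were alike in both batches. Rtp4 and Il6, which were under the count filter in batch 1 alone, had an adjusted p of 0.0525 and 0.0530 in edgeR's interaction test. Podn was at -0.95 in batch 1 alone and -0.52 in batch 2 alone. In simulated counts the interaction test recovered 22.4% of differences of 1.

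**Figure D2:**
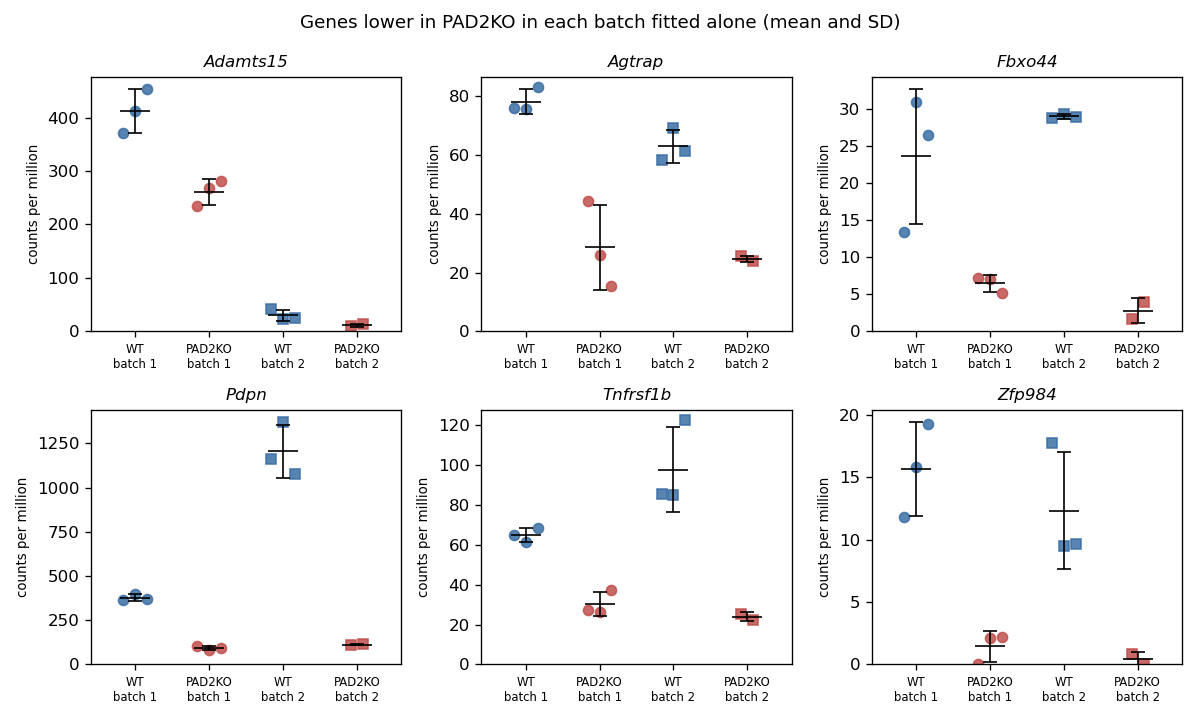
CPM of the 6 genes called lower in PAD2KO in each batch fitted alone, with a point per library (circles for batch 1, squares for batch 2) and bars for the mean and SD of each genotype and batch. Pdpn stood at 376 and 1204 CPM in WT and at 91.2 and 112 CPM in PAD2KO, and no PAD2KO library reached a WT library of its batch in any of the panels.

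Most of the genes that fell in both batches sit close to Padi2 in the genome. Padi2 lies on chromosome 4, and in the gene order of the GENCODE M21 annotation (GRCm38 assembly, where the submitters' notes name GRCm39) Pdpn is 18 tested genes from it, Tnfrsf1b 21, Zfp984 23, Agtrap 31 and Fbxo44 34. The window of 200 tested genes centred on Padi2, 100 on each side and chosen after these genes were seen, held 5 of the 19 calls where 0.397 were expected (Fisher's exact test, two-sided p = 3.45e-05). The highest count in any of 5392 other windows of that width was 3. Of the calls of batch 2 alone, the window held 9 of 228 with a position, where 4.76 were expected (Fisher's exact test, two-sided p = 0.0571), and 179 other windows held as many, up to 11. Of the 6 genes called in both batches, 5 lay in the window, against an expected 0.1252 (Fisher's exact test p = 2.22e-08). Between these genes lie others that went either way without passing the test, among them Zfp991 (-1.66), Miip (-0.75), Zfp933 (1.11) and Clcn6 (0.71), of which Zfp991 and Miip were chosen after their values were seen. On the other side of Padi2 and outside the window, chromosome 4 also holds Tnfsf15, Lepr and Podn, at -313, -262 and -240 tested genes from it. With these, 8 of the 19 calls lay on chromosome 4 where 1.18 were expected, and its 393 tested genes outside the window held 3 calls against 0.586 expected from the other chromosomes (Fisher's exact test, two-sided p = 0.0188). At an unadjusted p under 0.05 the window held 31 genes, 13 higher and 18 lower, against 15.4 expected. Zfp984, Zfp991 and Zfp933 are related zinc finger genes, so that reads can be shared between them and their values are uncertain. A list of genes flanking Padi2 closely, fixed beforehand, had a median of -0.12 over 16 genes and was not called by camera (adjusted p = 0.319). By fry's test for change in either direction it passed (adjusted p = 0.000139), as 10 other lists did, and adjusted over the list alone 1 gene was lower, Mfap2 (-0.58), named after its value was seen.

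**Figure D3:**
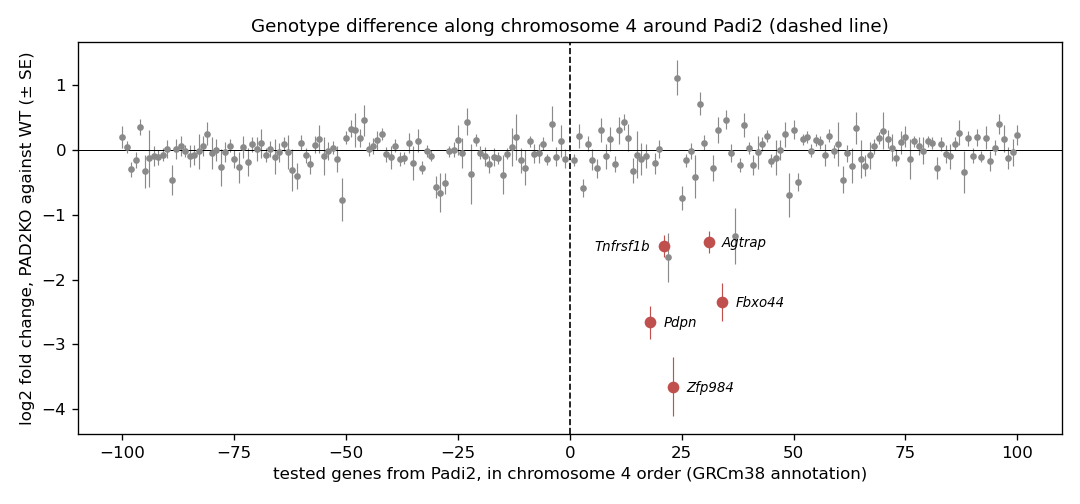
Log2 fold change of PAD2KO against WT, with its SE, for the 200 tested genes around Padi2 in chromosome order, counted from Padi2 at 0 (dashed line). The 5 genes past the false discovery rate (red) lie within 18 to 34 tested genes on a single side of Padi2.

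Inflammatory gene groups were lower in PAD2KO as groups in the fit of both batches and in batch 2, but not in batch 1. In batch 1 alone the medians were -0.05 for interferon-stimulated genes, 0.03 for the TNF and NF-kB response, -0.02 for MHC class I and -0.11 for complement, none of them called (adjusted p = 0.717, 0.907, 0.907 and 0.178 by camera). In batch 2 alone they were -2.05, -0.62, -1.01 and -0.79, all called, but none with a correlation between genes estimated in place of the preset 0.01. The fall of the TNF and NF-kB response in batch 2 lay mostly in PAD2KO 7. Its mean centred log2 CPM was 0.871 in PAD2KO 6 and -0.274 in PAD2KO 7, beside 0.989, 1.14 and 1.27 in WT 5, WT 6 and WT 7. Of 28 interferon-stimulated genes tested, 1 passed over all genes and 12 passed adjusted over the list alone, all lower, with a median of -0.81 (adjusted p = 6.91e-17 by camera; 0.559 with an estimated correlation). The 1 gene was Rtp4, an interferon-induced chaperone of receptors, which fell by 2.23 (adjusted p = 0.0178; -1.12 and not called with 1 surrogate variable). Xaf1 (-0.98), Parp14 (-1.10) and Iigp1 (-0.77) did not pass over all genes. The TNF and NF-kB response had a median of -0.28 over 30 genes (adjusted p = 2.72e-05; 0.559 with an estimated correlation), with Tnfrsf1b and Il6 past the threshold and lower, and adjusted over the list alone 1 gene higher and 2 lower. Il6, the inflammatory cytokine interleukin 6, fell by 1.61 (adjusted p = 0.0394; -0.67 and not called with 1 surrogate variable) but was lower in 3 of 5 PAD2KO libraries, at 3.32 and 3.66 CPM in WT and PAD2KO of batch 1 and 66.0 and 15 CPM in batch 2. Complement genes had a median of -0.35 over 10 genes (adjusted p = 2.16e-05; 0.559 with an estimated correlation), 1 of which, C2, fell by 0.99 (adjusted p = 0.0163), while 2 passed adjusted over the list alone. MHC class I and its peptide loading genes had a median of -0.47 over 11 genes (adjusted p = 0.000130; 0.559 with an estimated correlation), with H2-T22 at -0.70 and Tap1 at -0.47 and none past the threshold. Chemokines (median -0.35 over 8 genes, adjusted p = 0.225) and cytokines with their receptors (-0.09 over 18, adjusted p = 0.106) were not called.

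Contractile and mitotic groups were higher in PAD2KO as groups in the fit of both batches and in batch 2. In the fit of both batches without an interaction term, no single member passed the threshold over all genes. In batch 2 alone 10 contractile genes and 2 mitosis genes were higher past the threshold, and neither group was called there with an estimated correlation (adjusted p = 0.413 for both). In batch 1 alone contractile genes went the other way and were called lower (median -0.12, adjusted p = 0.0128; 0.947 with an estimated correlation). The medians were 0.28 for 19 contractile genes (adjusted p = 2.72e-05), 0.32 for 10 markers of airway and vascular smooth muscle (adjusted p = 0.00128), 0.19 for 25 G2/M and mitosis genes (adjusted p = 0.00178), 0.16 for 19 targets of YAP and SRF (adjusted p = 0.00201), 0.12 for 23 glycolysis and hypoxia genes (adjusted p = 0.00434) and 0.20 for 13 mitochondrially encoded mRNAs (adjusted p = 0.0218). With an estimated correlation none was called, the adjusted p being 0.585 for contractile genes, 0.700 for mitosis and mitochondrial mRNAs and 0.559 for the other three. Examples are Acta2, smooth muscle actin, at 0.61, the tropomyosin Tpm2 at 0.28, Ccn1 at 0.32, the mitotic kinase Aurka at 0.49 and the hypoxia-induced peptide gene Adm at 0.33. Adjusted over the list alone, 0 genes passed in these groups but for 1 of the glycolysis and hypoxia genes, which was higher. In all, 10 of 45 lists tested were called, 6 higher and 4 lower. Without PAD2KO 7 the number was 5, and contractile genes (median 0.13), YAP and SRF targets (0.09), TNF and NF-kB response (-0.08), mitosis (0.13) and smooth muscle (0.19) were no longer called. Mitosis genes were not called either without WT 1 (0.11), PAD2KO 2 (0.13) or PAD2KO 3 (0.13), smooth muscle markers without PAD2KO 6 (0.26), glycolysis and hypoxia genes without PAD2KO 2 (0.07), and mitochondrial mRNAs without WT 4 (0.15), WT 7 (0.11), PAD2KO 1 (0.12), PAD2KO 3 (0.18) or PAD2KO 6 (0.15). In batch 1 alone smooth muscle markers (-0.12), YAP and SRF targets (-0.0110), mitosis genes (0.03) and mitochondrial mRNAs (0.12) were not called, and glycolysis and hypoxia genes were higher there (0.24, adjusted p = 1.36e-05; 0.450 with an estimated correlation) but not in batch 2 alone (-0.0641).

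The genotype difference was not the same in the 2 batches, and the interferon and contractile groups were among those that differed. In batch 2, where WT fibroblasts expressed interferon-stimulated genes highly, PAD2KO fibroblasts did not: Ifi44, an interferon-induced gene, stood at 65.0 ± 23.7 CPM in WT and 6.90 ± 3.01 CPM in PAD2KO (SD, n = 3 and 2). In batch 1 it stood at 5.36 ± 1.19 and 7.72 ± 0.923 CPM (SD, n = 3 and 3). Contractile genes went the other way: Acta2 was at 1247 ± 114 CPM in WT and 3500 ± 647 CPM in PAD2KO of batch 2, but at 5189 ± 213 and 4757 ± 1080 CPM in batch 1. The interaction of genotype and batch passed the false discovery rate for 161 genes in edgeR's test, positive for 66 and negative for 95, a positive value standing for a higher difference of PAD2KO from WT in batch 2. Without PAD2KO 7 the count was 33, of which 31 were among the 161, with PAD2KO 6 as the lone PAD2KO library of batch 2 and assumed to vary as the other groups did. Without WT 3 the count was 93 and without PAD2KO 3 it was 102. The genes named here were picked after their values were seen from the group members and from the largest changes.

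Of 28 interferon-stimulated genes, 10 had a negative interaction past the threshold and 26 passed adjusted over the list alone. The median was -1.70 (adjusted p = 1.44e-28; adjusted p = 0.146 with an estimated correlation), made of -0.06 in batch 1 and -1.77 in batch 2 in the joint fit. The interaction was -3.71 for Ifi44 (SE 0.578, adjusted p = 0.000483), -3.20 for Ifit1, -2.13 for Oasl2 and -1.98 for Stat2. Without PAD2KO 7 the calls of Ifit1 (-3.04), Oasl2 (-1.56) and Stat2 (-1.58) were lost, and the median of the group was -1.57 and still called. Leaving out WT 1, WT 4, PAD2KO 1 or PAD2KO 3 also ended the calls of Ifit1 and Oasl2, and leaving out PAD2KO 2 that of Ifit1, with values of -3.31 to -3.06 for Ifit1 and -2.18 to -1.96 for Oasl2. MHC class I genes had a median of -0.92 (adjusted p = 1.90e-06; adjusted p = 0.146 with an estimated correlation), with 3 of 11 genes past the threshold and 7 adjusted over the list alone. B2m, the light chain of class I molecules, was at -1.13 and H2-K1 at -1.85, the latter not called without PAD2KO 7 (-1.80), WT 6 (-1.84), PAD2KO 2 (-1.74) or PAD2KO 3 (-1.77). Macrophage and monocyte markers took 0.0378% of the counts in WT 7, 0.0126% in WT 5, 0.0146% in WT 6, 0.0135% in PAD2KO 6 and 0.00851% in PAD2KO 7.

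Contractile genes had a positive interaction past the threshold in 9 of 19 and in 16 adjusted over the list alone. The median was 0.99 (adjusted p = 3.96e-17; adjusted p = 0.146 with an estimated correlation), from -0.13 in batch 1 to 0.90 in batch 2, where 12 genes were higher in PAD2KO. Acta2 (1.61, SE 0.206, adjusted p = 0.000480), Cnn1, the smooth muscle calponin (1.53, SE 0.187, adjusted p = 8.53e-05), and Vcl, the focal adhesion protein vinculin (1.13, SE 0.175, adjusted p = 0.000483), were called with and without PAD2KO 7. Myh11, smooth muscle myosin, at 2.23 lost its call without PAD2KO 7 (2.07) as did Itga1, a collagen-binding integrin, at 1.69 (1.33 without it), and Myh11 also lost it without WT 1, WT 5, WT 6, WT 7 or PAD2KO 3 (2.19 to 2.26). Smooth muscle markers, several of them contractile genes too, had a median of 1.37 (adjusted p = 8.13e-11; adjusted p = 0.146 with an estimated correlation), with 4 of 10 genes past the threshold. Cholesterol synthesis genes had opposite signs in the batches, with a median of 0.28 in batch 1 and -0.50 in batch 2. Their median interaction was -0.83 (adjusted p = 2.37e-15; adjusted p = 0.146 with an estimated correlation), with 7 of 22 genes past the threshold and 17 adjusted over the list alone. Idi1, an isomerase of this pathway, was at -1.22, with its call lost without PAD2KO 7 (-1.02), and Scd1, the stearoyl-CoA desaturase, at -1.26 (SE 0.163, adjusted p = 0.000107).

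**Figure D4:**
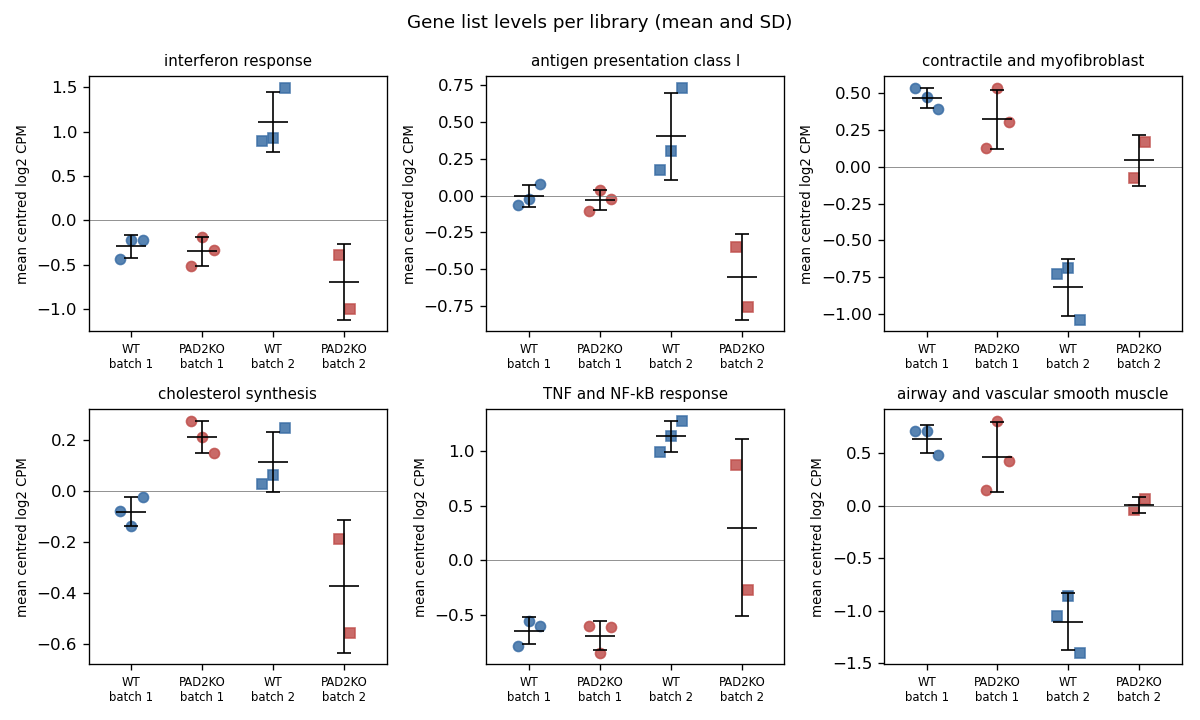
Mean centred log2 CPM of the members of 6 gene groups, with a point per library (circles for batch 1, squares for batch 2) and bars for the mean and SD of each genotype and batch. Interferon-stimulated genes stood at 0.89, 0.93 and 1.497 in WT 5, WT 6 and WT 7 and at -0.39 and -0.998 in PAD2KO 6 and PAD2KO 7, and contractile genes lay lowest in the WT libraries of batch 2.

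Batch 2 fibroblasts differed from batch 1 fibroblasts in far more genes than PAD2KO did from WT. TNF response, glycolytic and replication genes were higher in batch 2 as groups, and collagen, matrix glycoprotein, contractile and complement genes lower. In edgeR's test 2960 of 9932 genes differed, 1503 higher and 1457 lower in batch 2. The cytokine genes Il11 (5.39, SE 0.273), Lif (3.50) and Il6 (3.41), the chemokine gene Ccl2 (3.94), the thyroid hormone deiodinase Dio2 (4.09) and the collagenase Mmp13 (2.78) rose on the log2 scale, as did the glucose transporter Slc2a1 (1.26), the oxidative stress enzyme Nqo1 (2.11) and Rrm2, a subunit of ribonucleotide reductase (1.08). Podn (-4.66), the small proteoglycan gene Ogn (-4.20), Bmp3 (-4.00), Adamts15 (-3.98), Vegfd (-3.55), Col3a1 (-2.31), Myh11 (-2.02), Igf1 (-1.83) and Acta2 (-1.31) fell. These genes were picked after their values were seen, by size and by gene group. For Acta2 and Myh11 the interaction with genotype passed its test (1.61 and 2.23), so a single batch value does not describe each genotype. Of 30 TNF and NF-kB response genes, 20 were higher and 1 lower (median 1.21, adjusted p = 1.64e-08; adjusted p = 0.259 with an estimated correlation). Of 10 complement genes 1 was higher and 6 were lower (median -0.86, adjusted p = 0.00172; adjusted p = 0.259 with an estimated correlation). Cytokines and their receptors (-0.29, 5 higher and 8 lower of 18) and matrix proteases and their inhibitors (0.55, 11 higher and 6 lower of 21) were not called as groups. Of 23 glycolysis and hypoxia genes 17 were higher (median 0.84; adjusted p = 0.155 with an estimated correlation), of 17 collagens 1 was higher and 12 lower (median -0.76; adjusted p = 0.165 with an estimated correlation), and of 33 matrix glycoproteins 3 were higher and 20 lower (median -0.58; adjusted p = 0.0827 with an estimated correlation). Of 24 G1/S and DNA replication genes 17 were higher (median 0.53; adjusted p = 0.259 with an estimated correlation), and of 19 contractile genes 14 were lower (median -0.93; adjusted p = 0.382 with an estimated correlation).

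Library totals, genes seen, shares of technical gene groups and shares of cell type markers gave no measure past the threshold between the genotypes. Of 29 such measures, 0 reached an unadjusted p under 0.05 between 6 WT and 5 PAD2KO libraries in exact permutation tests, two-sided, and the lowest adjusted p was 0.889. With genotypes exchanged within batches only, 2 of 29 reached an unadjusted p under 0.05 over 200 splits, those of pericyte markers (exact p = 0.0200) and adventitial fibroblast markers (exact p = 0.0350), and the lowest adjusted p was 0.435. In batch 2 alone 9 measures were at the smallest p that 3 against 2 libraries can give, with 2.9 expected by chance, while in batch 1 alone 1 was, that of alveolar fibroblast markers. The 9 included markers of smooth muscle at 0.208% ± 0.0315 in WT and 0.541% ± 0.0892 in PAD2KO, of mesothelium at 0.231% ± 0.0229 and 0.155% ± 0.0293, and of adventitial fibroblasts at 0.175% ± 0.0197 and 0.117% ± 0.0150 (SD, n = 3 and 2). The other 6 were markers of general fibroblasts, alveolar fibroblasts, alveolar myofibroblasts, pericytes and epithelium and the immediate early genes. The tests over all 11 libraries, made between the batches, gave 14 measures past an adjusted 0.05, whose smallest possible p was 0.00217. Markers of neutrophils and mast cells took 0.0913%, 0.0971% and 0.0464% of the counts in WT 5, WT 6 and WT 7 and 0.0598% and 0.0636% in PAD2KO 6 and PAD2KO 7, and less than these in every library of batch 1. General fibroblast markers took 2.08% ± 0.298 in WT and 1.80% ± 0.0906 in PAD2KO of batch 1 (SD, n = 3 and 3), and 1.22% ± 0.0463 and 1.09% ± 0.0602 in batch 2 (SD, n = 3 and 2). Within a batch, 3 against 3 and 3 against 2 libraries cannot give an exact p under 0.1.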

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

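All tests of explanations in this part, and the splits of the samples, were chosen only after the results they bear on were seen; leaving out each library and DESeq2 were planned.

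The first pattern is the run of lower genes beside Padi2. If DNA of another mouse strain had travelled with the targeted allele, calls would gather around Padi2, and the window of 200 tested genes around it held 5 calls where the highest other window held 3, which is consistent with such linked strain DNA; sequence variants that would settle it were not analysed here. Reads shared between zinc finger genes cannot account for the stretch, since 4 of its 5 calls are not zinc finger genes, though they could still affect Zfp984. Linked DNA could reach beyond the window to Tnfsf15, Lepr and Podn (3 calls on the rest of chromosome 4 against 0.586 expected), while the 11 calls on other chromosomes are not linked to Padi2 and may come from loss of PAD2 or from strain differences elsewhere, which were not tested. Padi2 had only 3 counts over all WT libraries and 9 over all PAD2KO libraries, so loss of its mRNA was not itself seen in these cells. For the genes on chromosome 4, loss of PAD2 and linked DNA cannot be told apart, because any DNA linked to the allele would be in every PAD2KO library, and no comparison here parts the 2 for Pdpn or Tnfrsf1b.

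The second pattern is the genotype difference that differs between the batches, seen in 161 genes and 15 gene lists (0 lists with an estimated correlation) by a test of the interaction itself. Whether PAD2KO 7 alone accounts for it was not settled. Of the genes picked in the fit without PAD2KO 6, 98.3% had the same sign in the fit without PAD2KO 7. Their median there was 0.778 against 1.303. An interval of 0.694 to 0.870 for it came from resampling these genes within the same libraries. It carries no spread between libraries and treats correlated genes as separate. Simulated sets in which PAD2KO 7 alone departed gave at most 80.4% and medians of at most 0.303. There were 20 sets for each of 3 sizes of departure. Of these sizes, 1 was scaled to call about as many genes as the real libraries. The real agreement was higher than such a departure gave in simulation. The simulated genes were drawn independently, however, while real interferon-stimulated and contractile genes were correlated and can share a sign by chance. The simulated limits may thus be too low, and no conclusion on PAD2KO 7 is drawn from them. Both real fits share the WT libraries of batch 2, so a shift common to those libraries would give shared signs too. The simulated sets held no such shift, so they cannot part it from a difference shared by PAD2KO 6 and PAD2KO 7. Each of these fits keeps a lone PAD2KO library in batch 2 that is assumed to vary like the other groups, and the size of the count does rest on PAD2KO 7, since 33 genes were called without it, 93 without WT 3 and 102 without PAD2KO 3. Most of the calls did not rest on Xist level or on unequal depth. Of the 161 calls, 139 were kept with Xist as a covariate and 114 with every library thinned to the smallest total. The Xist term was the same in both batches, so a sex difference that itself differs between batches was not tested. The part of PAD2KO 7, and of a shift common to the WT libraries of batch 2, stays open. Also open and untested is any difference in culture, sort or handling between batches that met the genotypes unequally. The same holds for a response of PAD2KO cells that appears only in the state of batch 2.

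Chance was weighed with 100 of the 462 splits of the libraries, or of the 200 that keep the batches. For PAD2KO against WT, 1 split, the real one, gave as many as 19 genes, the highest other giving 14. Within batches it was again 1, the highest other giving 7. Among the splits drawn, chance thus gave no count of genes as high. The remaining splits were not fitted. Splits of libraries also cannot exclude a difference between animals or cultures that several libraries share. For the 10 gene lists chance cannot be excluded, since 38 splits gave as many, up to 17. For the interaction, 1 split gave as many as 161 genes and the highest other 126. However, 8 of the other splits kept PAD2KO 6 and PAD2KO 7 together as the PAD2KO libraries of batch 2 and called 42 to 126 genes, and the 91 with another pair called at most 8, so most of the count follows a structure shared by those 2 libraries. They are 1 of the 10 pairs that batch 2 can give, so for that structure to fall on the genotype chance cannot be excluded. For the 15 interaction lists chance cannot be excluded, with 10 splits as high and up to 18 lists. For the batch term 1 split gave as many as 2960 genes, the highest other giving 1764 and the median of the others 0.

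The lists whose genotype difference passed the interaction test, with their median difference between the batches, were collagens (0.45), contractile genes (0.99), YAP and SRF targets (0.42), TNF and NF-kB response (-0.59), interferon response (-1.70), MHC class I (-0.92), complement (-0.75), G2/M and mitosis (0.31), glycolysis and hypoxia (-0.32), cholesterol synthesis (-0.83), lipofibroblast and lipid storage (-0.32), metallothioneins (-1.66), alveolar fibroblast markers (0.57), smooth muscle markers (1.37) and neutrophil and mast cell markers (-2.78, from 3 genes tested). With an estimated correlation none passed, the lowest adjusted p being 0.146. Without PAD2KO 7, TNF and NF-kB response (-0.18), complement (-0.29) and G2/M (0.25) lost their call; G2/M also lost it without WT 4 (0.15) or PAD2KO 1 (0.12), and glycolysis and hypoxia without PAD2KO 6 (-0.25).

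Single genes with such a difference, on the log2 scale, were Acta2 (1.61), Cnn1 (1.53), Myh11 (2.23), Vcl (1.13), Itga1 (1.69), Col4a1 (0.96), Limch1 (1.55), Ifi44 (-3.71), Ifit1 (-3.20), Stat2 (-1.98), Oasl2 (-2.13), H2-K1 (-1.85), B2m (-1.13), Scd1 (-1.26), Idi1 (-1.22), Mt1 (-1.88), Grem1 (-1.27) and Pdpn (-1.38). Without PAD2KO 7 the calls of Myh11 (2.07), Itga1 (1.33), Col4a1 (0.68), Limch1 (1.28), Ifit1 (-3.04), Stat2 (-1.58), Oasl2 (-1.56), H2-K1 (-1.80), Idi1 (-1.02) and Mt1 (-1.74) were lost. Without at least 1 other library, so were those of Myh11, Col4a1, Ifit1, Oasl2, H2-K1 and Mt1, with the same sign.

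Of 128 sets of values tested per genotype over both batches, 7 held a library far from the others. Chance alone marks about 1 in 20 where the batches do not differ. Where they do differ, a library far from others of its batch can go unmarked. They were the share of counts from genes flanking Padi2 in PAD2KO 3 (0.133%), macrophage markers in WT 7 (0.0378%), cartilage and muscle markers in WT 7 (0.00634%), Fbxo44 in WT 1 (13.4 CPM), Adamts7 in PAD2KO 6 (103 CPM), and the mean log2 CPM of YAP and SRF targets in PAD2KO 7 (0.23) and of G2/M genes in PAD2KO 1 (-0.55).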

How the results depend on the processing

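The alternatives with Rn18s removed, gene length offsets, Xist, summed or thinned libraries, permutation within batches, and all for the interaction but DESeq2 and leaving out libraries, were chosen after seeing the data. For PAD2KO against WT (19 genes), every gene with a count gave 142 (51 higher, 91 lower; all 19 among them, and more genes near 0 tested), DESeq2 30 (18 shared), no batch term 4, 1 surrogate variable 10, batch 2 alone 248, gene length offsets 2 (SEs 1.31 times as large at the median, all 19 of the same sign) and a fold change of at least 2 as well 12; the cause was not tested beyond these values and constructions. Leaving out each library gave 8 (without WT 3) to 26 (without WT 1), and the other settings stayed within 1.5 times but for the replicate number as a block (4). Summing WT 5 and WT 6 gave 13 genes, 12 of them among the 19. Adamts7, Anxa1, Dchs1 and Tnfsf15 lost their call there, and Il6, Rtp4 and Rab6b were not tested. The gene lists (10) numbered 6 in batch 1 alone, 16 in batch 2 alone, 0 with an estimated correlation, 0 by fry (11 by its test for change in either direction) and 5 to 11 leaving out a library (5 without PAD2KO 7). In batch 1 alone the medians of contractile genes (-0.12), YAP and SRF targets (-0.0110) and smooth muscle markers (-0.12), and the values of Tpm2 (-0.0359) and Acta2 (-0.12), reversed, as did the median, though not the direction by camera, of the TNF and NF-kB response (0.0276), and glycolysis and hypoxia in batch 2 alone (-0.0641), and all of these passed the interaction test. For the interaction (161 genes; 15 lists), leaving out each library gave 33 (without PAD2KO 7) to 233 (without PAD2KO 6) genes and 13 to 18 lists, and an estimated correlation 0 lists. With that block PAD2KO against WT gave 4 genes (3 shared) and the interaction 112 (93 shared). The labels do not say that the numbers pair the libraries, and deviations of like-numbered libraries correlated at only 0.00152 to 0.0487. In a search for the best match, 0 of 4 matched best with their own number. That search took in PAD2KO libraries of the other batch, so it cannot tell whether the numbers pair. The batch count (2960) was 2526 with DESeq2 and 2532 to 2949 leaving out a library. Other scalings moved the median of all genes by little, to between -0.00169 and 0.0104. Padi2 gave no value under the alternatives set for its fold change, all of which keep the count filter. At this depth 0 counts in a library allow a level of up to 2.11 to 3.12 CPM. In simulated counts a genotype difference that differed by 1 between the batches was mostly uncalled (22.4% recovered).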

Other observations

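The values in this part were looked at after the other results were seen, and no explanation was tested.

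Several groups were not called for PAD2KO against WT, for the interaction or in either batch alone. Cytosolic ribosomal protein genes had a median of 0.00 over 32 genes for PAD2KO against WT, nuclear-encoded respiratory chain genes -0.03 over 30, p53 targets 0.00 over 15, and unfolded protein response genes -0.01 over 18, with 0 genes past the threshold in each. Collagens were not called either in the fit of both batches without an interaction term. They were called lower in batch 1 alone (-0.17, adjusted p = 0.0164 by camera, 0.882 with an estimated correlation) and lay at 0.17 in batch 2 alone. The difference between batches passed its test (0.45, adjusted p = 0.00523 by camera, 0.285 with an estimated correlation). In the fit without that term collagens had a median of -0.04 over 17 genes, with 2 genes lower adjusted over the list alone. Col3a1 was at -0.38 (adjusted p = 0.147) and Col14a1 at -0.68 (adjusted p = 0.165) in edgeR's test. TGF-beta response genes had a median of 0.06 over 23 (adjusted p = 0.0510 by camera). In batch 2 alone they were called higher (0.26, adjusted p = 0.00469 by camera, 0.413 with an estimated correlation), with 3 genes higher and 1 lower. Snai2 was at 0.64 in the fit of both batches without an interaction term (adjusted p = 0.177 in edgeR's test). Among imprinted genes Peg10, a retrotransposon-derived gene, fell by 0.83 (adjusted p = 0.0216), while Grb10, a growth-restricting adaptor, was at 0.62 and did not pass.

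Xist and the Y-linked genes divided the libraries without regard to genotype. Xist had 742 counts in WT 1, 17 in WT 3, 10 in WT 4, 482 in WT 5, 426 in WT 6 and 128 in WT 7, and 3 in PAD2KO 1, 8 in PAD2KO 2, 750 in PAD2KO 3, 528 in PAD2KO 6 and 404 in PAD2KO 7. Ddx3y had 95 and 71 counts in WT 3 and WT 4, 94 and 93 in PAD2KO 1 and PAD2KO 2, 32 in WT 7 and at most 4 in the others. WT 7 thus carried both kinds, and it also had the highest share of macrophage markers (0.0378%).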
